A study of Mus musculus with 12 samples.

How the data were processed

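Total RNA from whole liver was measured on 12 Affymetrix 430A arrays, 1 array per pool of 3 male C57BL/6 or POR-null mice, with 3 pools for each of 4 groups: wild type and POR-null, each on the control diet or on a quercetin diet. Groups and pool numbers were taken from the sample titles. Strain background was not a term of the model. The genotype contrasts therefore cannot separate loss of POR from any difference in strain background. The deposited values are on a log2 scale, as their range from 2.57 to 14.2 shows, and the submitters' processing notes name MAS5 and RMA without a version or a role for either. Which of these the authors used to make the deposited log2 values, and their background correction, are not given in the sources used here. Array medians lay between 5.93 and 5.99, no array was a copy of another, and no further normalization was applied before the tests. Since the values were already logarithmic, no pseudocount was added, and the planned comparison of pseudocounts did not apply.

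The table held 22690 probe sets, of which 64 were AFFX controls and 22626 were tested. In the platform annotation 20380 of all probe sets carried 1 gene symbol, 691 carried several and 1555 carried none; probe sets with several or no symbols were tested but not named. Symbols were matched by gene identifier to the GRCm38.p6 RefSeq gene table for 20351 probe sets, which changed 0 symbols, and 29 kept the name of the platform annotation. The single-symbol probe sets covered 12393 genes, and each gene was represented by its probe set with the highest mean over all 12 arrays. Por, the disrupted gene, was not analysed here, so the genotype labels were not checked by the level of the disrupted gene. No reference genome was used and no coordinates are given.

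Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group fitted over all 12 arrays, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over the 22626 probe sets at an adjusted p of 0.05. All tests were two-sided. The contrasts were quercetin against control diet in each genotype, the average of both, their difference (the interaction), and POR-null against wild type on each diet. Fold changes are differences of log2 means, given with the moderated SE, and group values are log2 mean ± SD. Over the probe sets the 95% confidence interval of a difference between a pair of groups had a median half-width of 0.24 log2 units, and the number of arrays limits this precision. The p-values measure the spread between pools of mice, not between single mice.

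Before the data were examined, 31 gene lists were fixed, covering drug metabolism, lipid, bile acid, glucose and amino acid pathways, stress and inflammatory responses, sex-biased liver genes, and markers of other cell types and tissues. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, which compares a list with all other genes, adjusted over the 31 lists within a contrast. Each was repeated with an estimated inter-gene correlation and with limma's fry, which tests whether a list's genes move one way on balance and makes no comparison with other genes. Members were counted by the limma fit, adjusted over all probe sets and adjusted over the list alone. Lists for the quercetin-diet genotype contrast, the genotype contrast averaged over diets and exact permutations of list means were added after seeing the data.

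Genes were named by a rule fixed beforehand, among genes past the threshold whose higher group mean exceeded the median of all values (5.96). They were the 12 largest increases and 12 largest decreases of quercetin in either genotype and of the control-diet genotype contrast, and 5 of each for the other contrasts. Up to 4 members per list with the lowest p, a fixed set of drug metabolism genes and, where fewer than 10 genes passed, the 5 genes per direction with the lowest p and no overlap between the groups' arrays were added. Further list members quoted as examples were chosen after their values were seen.

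The alternatives were a filter leaving out the 40% of probe sets with the lowest means, quantile normalization, a variance prior without trend or with robust estimation, array weights, the pool number as a block, fits of only the groups compared, genes in place of probe sets, and leaving out each array in turn. The procedure was tested on simulated data built for quercetin in wild type with the real residual spread of the 22626 probe sets. In it limma recovered 49.6% of probe sets changed by 0.5 log2 units and 95.0% of those changed by 1 log2 unit, with a mean of 8 false calls per run over 5 runs of 200 changed probe sets. Camera called a list shifted by 0.25 log2 units in 20 of 20 runs. Other lists were called 9 times over all runs. Some of them share members with the shifted list, so not every such call need be false. The simulated genes were independent, which favours the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.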

Results

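Gene expression was measured in liver of mice with an intact or a disrupted gene for cytochrome P450 reductase (POR), the enzyme that passes electrons to the microsomal cytochromes P450. After 14 days of adaptation to a soya-free powdered diet, mice aged 6 to 8 weeks stayed on it or received it with quercetin, a plant flavonol, at 6.2 g per kg (given also as 7 mg per mouse), and livers were taken after 24 h. Each of the 4 groups held 3 arrays, and each array carried the pooled RNA of 3 mice. Arrays of one group correlated at r = 0.988 to 0.993 across probe sets. The first principal component (33.0% of the variance) separated the genotypes. The second (12.4%) set wild-type control arrays 2 and 3 (-17.7 and -16.2) apart from wild-type control array 1 (12.1) and from the wild-type quercetin arrays (8.14 to 16.9). POR-null control array 3 lay nearest to wild type on the first component, at 0.11 against 19.3 and 7.88 for the other POR-null control arrays. The 3′ minus 5′ log2 difference of the beta-actin control, a sign of RNA integrity, was 0.92 ± 0.08 in wild-type control, 0.84 ± 0.05 in wild-type quercetin, 0.97 ± 0.05 in POR-null control and 0.92 ± 0.10 in POR-null quercetin (SD, n = 3). That of the transferrin receptor control was 1.05 ± 0.07, 1.18 ± 0.11, 1.28 ± 0.10 and 1.28 ± 0.09 in the same order, with higher means in POR-null than in wild type. That of the Pcx control was 2.21 ± 0.44, 2.35 ± 0.20, 2.15 ± 0.28 and 2.01 ± 0.12, with lower means in POR-null. For Gapdh it was -0.19 ± 0.02, -0.17 ± 0.04, -0.15 ± 0.01 and -0.16 ± 0.05. In wild-type control the Pcx value was 1.72 in array 1 against 2.578 and 2.335 in arrays 2 and 3. These differences were not tested.

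**Figure D1:**
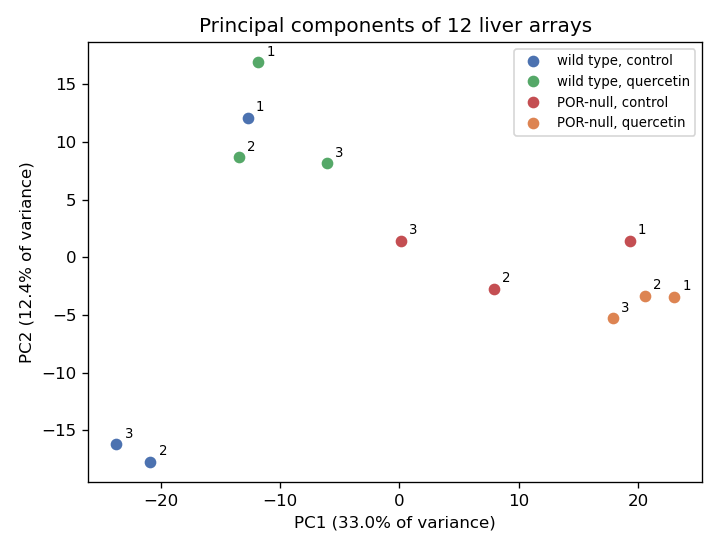
Each point is 1 of 12 liver arrays, numbered by pool within its group, on the first (x axis, 33.0% of variance) and second (y axis, 12.4%) principal components of the log2 values. POR-null arrays lie at 0.11 to 23.0 on the first component and wild-type arrays at -23.7 to -6.11, and wild-type control arrays 2 and 3 lie below the other wild-type arrays on the second.

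The first comparison asked how wild-type liver responded to quercetin. Genes of the urea cycle and amino acid breakdown were shifted upward: 20 of 24 measured members lay above their control-diet mean, with a median log2 difference of 0.25. As a list they passed with the preset but not with an estimated correlation (adjusted p = 0.0507), and 0 members passed over all probe sets. Hal, which starts histidine breakdown, differed by 0.90 ± 0.16 (SE, 3 arrays per group) and Got1, an aspartate aminotransferase, by 0.79 ± 0.18. Arg1 (arginase) and Mat1a (methionine adenosyltransferase) differed by 0.41 ± 0.10 each. Cholesterol synthesis genes lay lower, with 3 of 19 members above 0 and a median of -0.34. Among them, Idi1 stood at -1.20 ± 0.59, Cyp51 at -1.18 ± 0.40 and Stard4 at -0.83 ± 0.21. All 15 heat shock genes lay lower (median -0.29), with Hspa1b at -1.33 ± 0.51. The circadian clock genes had 4 of 18 members above 0 (median -0.21), with the clock output gene Dbp at -1.48 ± 0.51.

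By camera with the preset correlation 8 lists were called, of which 7 did not pass by fry. The urea cycle and amino acid list passed both (adjusted p = 3.92e-09 and 0.0159) but not camera with an estimated correlation (0.0507). Of its members 9 were higher when adjusted over the list alone. Heat shock genes were lower at camera adjusted p = 2.24e-05 (adjusted p = 0.649 with an estimated correlation). Cholesterol synthesis genes were lower at 2.56e-05 (adjusted p = 0.659 with an estimated correlation) and clock genes at 0.000564 (adjusted p = 0.461 with an estimated correlation). Fatty acid synthesis genes were lower at 0.00107 (adjusted p = 0.596 with an estimated correlation). NRF2 and glutathione genes were lower at 0.0328 (adjusted p = 0.659 with an estimated correlation). Bile acid and biliary transport genes (19 of 24 above 0, median 0.17) and macrophage and Kupffer cell markers (17 of 20 above 0, median 0.22) were higher. Their camera adjusted p were 0.000564 and 0.00105, with adjusted p = 0.284 and 0.725 with an estimated correlation. Adjusted over the list alone, members passing were 1 cholesterol synthesis gene lower, 2 clock genes lower, and 2 fatty acid synthesis genes lower and 1 higher. By the same count 1 NRF2 and glutathione gene was lower, 1 bile acid gene was higher, and 0 heat shock genes and 0 macrophage markers passed. The macrophage call rested on wild-type quercetin array 3 (list mean 0.39 against -0.26 and -0.21 in arrays 1 and 2), with adjusted p = 0.837 without it. Without wild-type control array 2 or wild-type quercetin array 1 the fatty acid synthesis list did not pass (adjusted p = 0.0561 and 0.079). The NRF2 and glutathione list did not pass without wild-type control array 1 or 2 or wild-type quercetin array 1 (adjusted p up to 0.23). The mean of the cholesterol synthesis list, relative to all arrays, was 0.37 and 0.35 in wild-type control arrays 2 and 3 and -0.33 in array 1. Against wild-type control array 1 alone, a fit added after seeing the data, only the urea cycle and amino acid list of these 8 lists passed.

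Targets of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds, showed no detectable shift. Cyp1a1 differed by 0.08 ± 0.11, Cyp1a2 by -0.09 ± 0.19 and Nqo1 by 0.12 ± 0.12, and the list of 10 genes had camera adjusted p = 0.402. Besides Hal, the higher single genes with the lowest p were Gldc (0.85 ± 0.16), Kmo (0.66 ± 0.12), Etfrf1 (0.71 ± 0.13) and Sco2 (0.51 ± 0.10). The lower ones were Maff (-0.75 ± 0.12), Nampt (-0.76 ± 0.12), Deptor (-0.84 ± 0.14), Sult2b1 (-0.90 ± 0.17) and Gsta4 (-0.60 ± 0.11). None of these genes passed (adjusted p = 0.165 to 0.227). By limma 0 of 22626 probe sets passed (lowest adjusted p = 0.0783), while 1942 had an unadjusted p under 0.05 where chance gives 1131. The count rested on wild-type control array 1: without it 151 probe sets passed, 89 higher and 62 lower.

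In POR-null liver the urea cycle and amino acid genes again lay higher with quercetin, 20 of 24 members above 0 and a median log2 difference of 0.17. Cth (cystathionine gamma-lyase) stood at 0.45 ± 0.15 and Asl (argininosuccinate lyase) at 0.37 ± 0.19. Male-biased liver genes lay lower (1 of 16 above 0, median -0.40), among them Hsd3b5 at -1.47 ± 0.75 and the organic anion transporter Slco1a1 at -0.80 ± 0.28. Acute phase genes lay higher (22 of 27 above 0, median 0.18), led by Saa2 at 2.03 ± 0.74 and Lcn2 at 1.29 ± 0.51. Genes of oxidative phosphorylation differed by a median of 0.05 (40 of 51 above 0). All 11 markers of exocrine pancreas, a tissue next to the liver, were higher by a median of 0.69. Their mean relative to all arrays was 2.25 in POR-null quercetin array 3 against -0.61 and 0.05 in the other arrays of that group.

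These lists passed camera with the preset correlation at adjusted p = 1.16e-05 (urea cycle and amino acid), 5.49e-05 (male-biased), 0.000548 (acute phase), 0.00207 (oxidative phosphorylation) and 0.0199 (exocrine pancreas). None held with an estimated correlation, with adjusted p = 0.194, 0.771, 0.913, 0.815 and 0.913 with an estimated correlation in the same order. None held by fry either, where the urea cycle and amino acid list had adjusted p = 0.143. Of their members 0 passed over all probe sets or adjusted over the list alone. Without POR-null quercetin array 3 the median of the pancreas markers turned to -0.12 (adjusted p = 0.761), and that list also did not pass without POR-null control array 1 or 2. Without POR-null quercetin array 1 the acute phase list did not pass (adjusted p = 0.735). The median of the male-biased list shrank to -0.24 without POR-null quercetin array 1 and to -0.25 without POR-null control array 3, and the list still passed. The oxidative phosphorylation list did not pass without POR-null control array 3 or POR-null quercetin array 3 (adjusted p up to 0.104), nor after quantile normalization. By limma 0 probe sets passed (lowest adjusted p = 0.446) and 1581 had an unadjusted p under 0.05. The genes with the lowest p were Cyp26a1, a retinoic acid hydroxylase (0.91 ± 0.18), Mrap (0.94 ± 0.22), Tefm (0.58 ± 0.14), Tax1bp3 (0.51 ± 0.11) and Gfra1 (0.50 ± 0.11), all higher. On the lower side were Slc25a25 (-0.72 ± 0.18), Nrep (-0.61 ± 0.13), Ercc8 (-0.52 ± 0.11), Fabp1, the liver fatty acid binding protein (-0.45 ± 0.11), and Kcnh1 (-0.35 ± 0.08). None of them passed, at adjusted p = 0.446 to 0.607.

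Averaged over both genotypes, Hebp1 (0.49 ± 0.08), Gfra1 (0.49 ± 0.08), Gldc (0.57 ± 0.11), Sco2 (0.39 ± 0.07) and Gas5 (0.27 ± 0.06) were the higher genes with the lowest p, at adjusted p = 0.151 to 0.232. Dnpep, Bcl2l11, Itm2a, H2-M10.1 and Gm5802 lay lower, at log2 differences of -0.29 to -0.18 and adjusted p = 0.308 to 0.401. By limma 0 probe sets passed (lowest adjusted p = 0.151) and 2079 had an unadjusted p under 0.05; without wild-type control array 1, 24 passed. Across 12393 genes the log2 differences in wild type and in POR-null, which share no arrays, correlated at r = 0.129 (Spearman's rho = 0.12), with the same sign in 54.3%; genes are not independent replicates.

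Whether the response differed by genotype was tested as an interaction, the log2 response in POR-null minus that in wild type. Sdc4, a cell surface proteoglycan, differed by -2.20 ± 0.46, Kmo by -0.79 ± 0.17, Epb41l1 by -0.69 ± 0.16, Ercc8 by -0.68 ± 0.16 and Lcat by -0.57 ± 0.11. On the positive side Deptor differed by 1.01 ± 0.20, Maff by 0.73 ± 0.17, F11r by 0.71 ± 0.14, Ola1 by 0.64 ± 0.14 and Cxadr by 0.55 ± 0.12. None passed, at adjusted p = 0.601 to 0.672. The cholesterol synthesis list lay on opposite sides in the genotypes, at a median of -0.34 in wild type and 0.10 in POR-null. The POR-null side did not pass camera with the preset correlation (adjusted p = 0.769). Against wild-type control array 1 alone the mean shift in wild type was 0.0042 in place of -0.45. By limma 0 probe sets passed (lowest adjusted p = 0.254) and 1397 had an unadjusted p under 0.05. By camera with the preset correlation 7 lists were higher and 4 lower. None held, with a lowest adjusted p = 0.726 with an estimated correlation and 0.727 by fry.

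**Figure D2:**
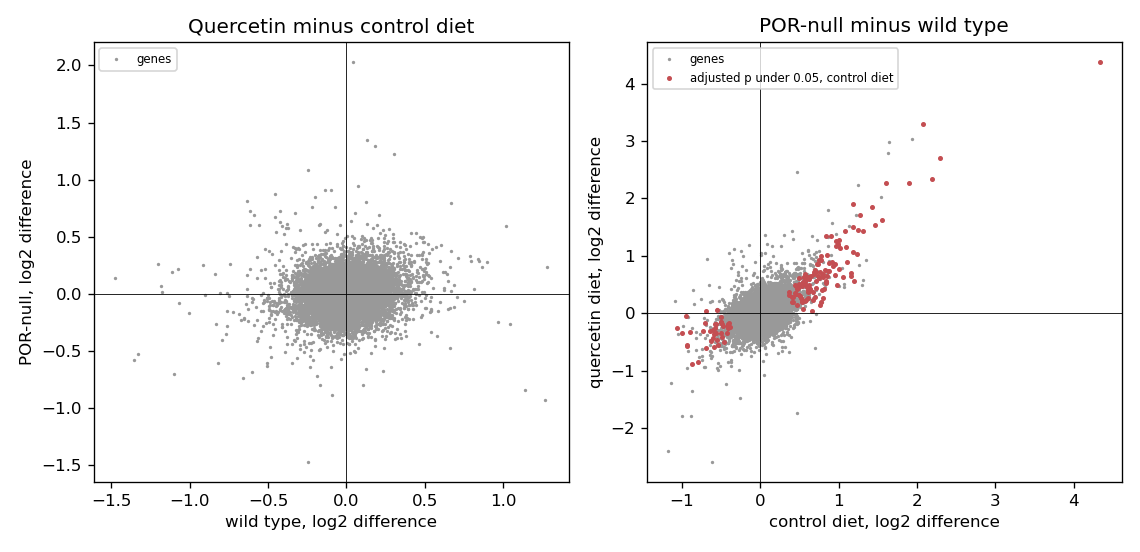
Each point is 1 of 12393 genes, with log2 differences on both axes. On the left, the quercetin response in wild type (x) is set against POR-null (y), r = 0.129; on the right, the genotype difference on the control diet (x) is set against the quercetin diet (y), r = 0.593, with genes at an adjusted p under 0.05 on the control diet in red.

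On the control diet POR-null liver differed from wild type in lipid droplet genes. Targets of CAR and PXR, nuclear receptors that induce drug metabolism, also differed, as a list with the preset but not with an estimated correlation. Cyp2b10, a classic CAR target, rose by 4.34 ± 0.40 log2 units (20.3-fold, adjusted p = 0.000148), from 7.72 to 12.1. Probe sets of this kind can also detect related transcripts. Of 24 measured CAR and PXR targets 6 rose, including Slco1a4 (1.18 ± 0.21), Aldh1a7 (1.00 ± 0.15), Aldh1a1 (0.58 ± 0.11) and Cyp3a11 (0.37 ± 0.08), and 0 fell. Cyp3a11 did not pass without wild-type control array 2 or 3 or POR-null control array 1 or 2 (adjusted p up to 0.178). Of 22 lipid droplet and steatosis genes 7 rose and 0 fell. The fatty acid transporter Cd36 rose by 1.89 ± 0.23, Anxa5 by 1.55 ± 0.29 and Apoa4 by 1.46 ± 0.27. The fatty acid binding protein Fabp4 rose by 1.25 ± 0.28 and the lipid droplet protein Cidec by 1.02 ± 0.16. Fabp4 passed in 1 of the 6 fits with an array left out, that without POR-null control array 3, and differed by 0.54 as the mean of its probe sets (adjusted p = 0.139). In fatty acid synthesis 4 of 25 rose, the lipogenic regulator Thrsp by 2.30 ± 0.30, the elongases Elovl5 by 1.16 ± 0.14 and Elovl6 by 0.76 ± 0.16, and pyruvate kinase Pklr by 0.72 ± 0.13.

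**Figure D3:**
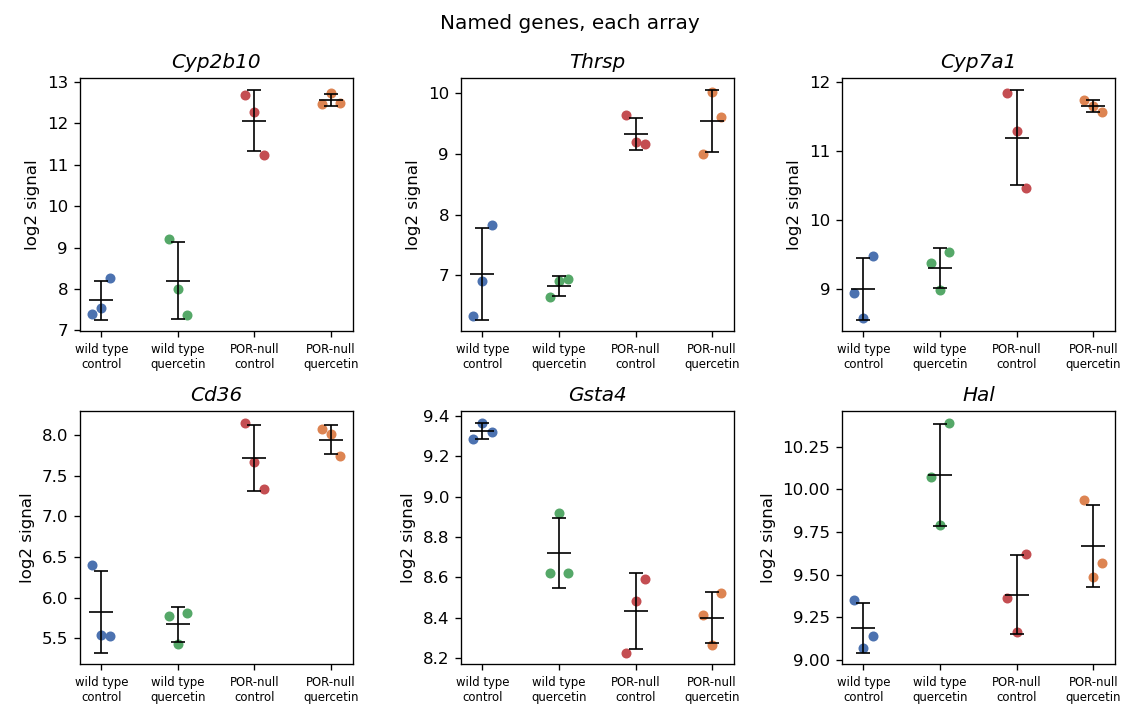
Log2 signal (y axis) of 6 genes in each array (points) of the 4 groups, with the mean and SD (bars, n = 3). Cyp2b10, Thrsp, Cyp7a1 and Cd36 are higher in POR-null on both diets; Hal and Gsta4 show the quercetin differences in wild type that did not pass.

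Of 24 bile acid genes 2 passed, both higher. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 2.19 ± 0.27 (4.58-fold, adjusted p = 0.00249), and Cyp8b1, the sterol 12-alpha-hydroxylase, by 1.18 ± 0.18. As a list the bile acid genes did not shift detectably, with 4 higher and 4 lower adjusted over the list alone. The estrogen sulfotransferase Sult1e1 rose by 2.08 ± 0.35, the metallothionein Mt1 by 1.61 ± 0.35, Lgals1 by 1.42 ± 0.25, Neat1 by 1.31 ± 0.27 and Gstm2 by 1.28 ± 0.25. None of these 5 genes passed in every fit with an array left out, and all 5 lost their call without wild-type control array 2 or POR-null control array 2. Mt1 and Lgals1 also did not pass without wild-type control array 3 or POR-null control array 1, nor Neat1 without the latter (adjusted p up to 0.201). As the mean of its probe sets Mt1 differed by 0.81 (adjusted p = 0.139). The amino acid enzymes Got1 and Oat rose by 1.16 ± 0.18 and 0.75 ± 0.08. Smaller increases passed for Mpeg1, Pygl, Papss2, Slc2a2, Cpt1a (the carnitine palmitoyltransferase of fatty acid oxidation), Car2, Sparc and Atp5pb. Among decreases, Gclc, which catalyses the first step of glutathione synthesis, fell by 0.88 on the log2 scale (SE 0.18) and Gsta4 by 0.89 (SE 0.11). Gdap10 (-1.06 ± 0.23), Sult2b1 (-0.95 ± 0.17), Etfbkmt (-0.94 ± 0.19), Nat8f1 (-0.93 ± 0.21) and Tmem141 (-0.79 ± 0.13) also fell, as did Nmnat1, Ccdc117, Spast, Maff, Wdfy2 and Herpud1. Gsta4, Sult2b1 and Maff were also among the lowest p for quercetin in wild type, a contrast that shares the wild-type control arrays. Targets of the aryl hydrocarbon receptor did not pass, with Cyp1a1 at 0.06 ± 0.11, Cyp1a2 at 0.26 ± 0.19 and Nqo1 at 0.11 ± 0.12.

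In total 262 probe sets passed by limma, 186 higher (148 genes) and 76 lower (68 genes). By camera with the preset correlation, CAR and PXR targets had adjusted p = 1.55e-12 (adjusted p = 0.103 with an estimated correlation), with 17 higher adjusted over the list alone. Lipid droplet genes had 1.55e-12 (adjusted p = 0.0112 with an estimated correlation), with 12 higher adjusted over the list alone, and were the only list to hold with an estimated correlation. The circadian clock list lay lower, with 0 of 18 members above 0 and 0 passing by either count (0.000272, adjusted p = 0.302 with an estimated correlation). Its means in wild-type control arrays 2 and 3 were 0.28 and 0.30 against 0.04 in array 1, and against array 1 alone the median shrank from -0.34 to -0.093 and the list did not pass. Macrophage and Kupffer cell markers lay higher, with Mpeg1 passing and 7 of 20 higher adjusted over the list alone (3.53e-05, adjusted p = 0.487 with an estimated correlation). Stellate cell and matrix markers lay higher with Sparc passing (0.00891, adjusted p = 0.487 with an estimated correlation), 3 adjusted over the list alone. The urea cycle and amino acid list was higher (0.000272, adjusted p = 0.185 with an estimated correlation), with 2 genes passing and 7 higher and 1 lower adjusted over the list alone. Fatty acid synthesis was higher (0.000872, adjusted p = 0.368 with an estimated correlation), with 6 higher and 1 lower adjusted over the list alone.

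Interferon response genes were higher (0.00152, adjusted p = 0.487 with an estimated correlation) with 0 by either count. PPARA and fatty acid oxidation genes were higher (0.00891, adjusted p = 0.487 with an estimated correlation) with 1 by either count. Conjugation genes were higher (0.0136, adjusted p = 0.487 with an estimated correlation), with 4 higher and 1 lower adjusted over the list alone. Female-biased genes were higher (0.0314, adjusted p = 0.368 with an estimated correlation), with 7 higher and 1 lower adjusted over the list alone. With single arrays left out, calls were lost for interferon genes (0.149 without POR-null control array 1) and PPARA genes (0.323 without wild-type control array 3). They were lost for conjugation genes without wild-type control array 3 or POR-null control array 1 (up to 0.248), and for female-biased genes without wild-type control array 1 or POR-null control array 2 (up to 0.104). Against wild-type control array 1 alone the macrophage, stellate cell, PPARA and conjugation lists also did not pass.

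Of the lists that passed camera on this diet, 8 did not pass by fry. The remaining lists did not pass camera. They were other microsomal P450 genes (adjusted p = 0.223), aryl hydrocarbon receptor targets (0.471), NRF2 and glutathione genes (0.50), cholesterol synthesis (0.57), bile acid genes (0.471) and glucose metabolism (0.223). The same held for acute phase (0.093), heat shock (0.291), ER stress (0.57), male-biased genes (0.50), oxidative phosphorylation (0.377) and cell cycle (0.599). Of other cells, tissues and secreted products it held for the lymphocyte (0.50), endothelial (0.131), cholangiocyte (0.50), erythroid (0.44), adipocyte (0.342), exocrine pancreas (0.877), intestinal (0.765) and hepatocyte secreted protein (0.675) lists. The count of calls moved with the fit and the arrays. When only these groups were fitted 30 probe sets passed, and 38 passed without wild-type control array 2, 67 without array 3, 35 and 62 without POR-null control arrays 1 and 2. The count rose to 756 without wild-type control array 1 and to 607 without POR-null control array 3. Cyp2b10, Thrsp, Cyp7a1 and Oat passed under every alternative run and with each array left out. Of 44 genes named as passing here, these, Cd36, Cyp8b1, Got1, Elovl5 and Gsta4 (9 in all) passed with each array left out, and the other 35 did not.

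**Figure D4:**
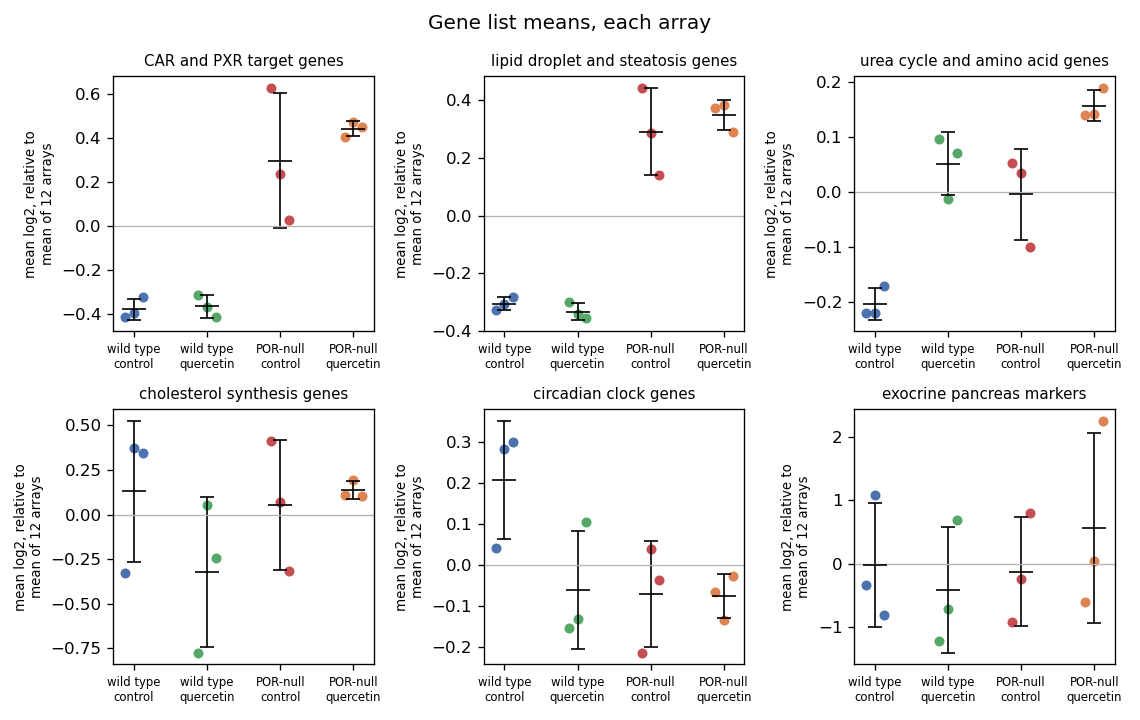
Mean log2 value of 6 gene lists in each array (points, relative to the mean of 12 arrays, y axis) by group, with the group mean and SD (bars, n = 3). CAR and PXR targets and lipid droplet genes are higher in every POR-null array than in every wild-type array; exocrine pancreas markers are highest in POR-null quercetin array 3, at 2.25.

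On the quercetin diet Cyp2b10 rose by 4.37 ± 0.40 (20.7-fold) and Sult1e1 by 3.29 ± 0.35. The acute phase genes Lcn2 and Orm2 rose by 3.04 ± 0.51 and 2.98 ± 0.49, the glutathione transferase Gstm3 by 2.79 ± 0.39 and Cyp7a1 by 2.34 ± 0.27. Ppp1r3c, a glycogen-targeting phosphatase subunit, fell by 2.60 on the log2 scale (SE 0.43), Hsd17b6 by 1.80 (SE 0.35), Slco1a1 by 1.79 (SE 0.28), Sdc4 by 1.73 (SE 0.33) and Nr0b2, a repressor of bile acid synthesis, by 1.35 (SE 0.21). With single arrays left out, Hsd17b6 did not pass without wild-type quercetin array 2 or 3 or POR-null quercetin array 1 or 2 (adjusted p up to 0.0724). Sdc4 did not pass without wild-type quercetin array 1 or 2 or POR-null quercetin array 2 (up to 0.0683). As means of their probe sets Hsd17b6 and Sdc4 differed by -0.97 and -0.85 and still passed. With a robust variance prior Lcn2, Orm2, Ppp1r3c, Hsd17b6 and Sdc4 did not pass (adjusted p = 0.0547 to 0.0821). Of CAR and PXR targets 11 of 24 rose, of lipid droplet genes 11 of 22 and of fatty acid synthesis genes 6 of 25, with 0 falling in each, and 2 of 16 male-biased genes fell, Slco1a1 among them. Cyp3a11 passed at 0.36 ± 0.08 with all arrays but not in any of the 6 fits with 1 array left out (adjusted p up to 0.10). Cyp1a1 (-0.07 ± 0.11), Cyp1a2 (0.47 ± 0.19) and Nqo1 (0.15 ± 0.12) did not pass.

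By limma 527 probe sets passed, 396 higher and 131 lower. List tests on this diet were added after seeing the data, and camera with the preset correlation called 14 lists higher and 1 lower. By fry 10 of these lists did not pass. Again only the lipid droplet list held with an estimated correlation (5.85e-14, adjusted p = 0.00731 with an estimated correlation), with 14 higher adjusted over the list alone. Members above 0 were 20 of 24 for CAR and PXR targets (1.13e-13, adjusted p = 0.077 with an estimated correlation), with 16 higher adjusted over the list alone. For fatty acid synthesis they were 23 of 25 (1.34e-09, adjusted p = 0.077 with an estimated correlation), with 11 higher adjusted over the list alone. For acute phase genes they were 17 of 27 (0.000737, adjusted p = 0.496 with an estimated correlation), with 4 higher over all and 8 adjusted over the list alone. Male-biased genes had 1 of 16 above 0 (0.000149, adjusted p = 0.341 with an estimated correlation), with 7 lower adjusted over the list alone. All 11 exocrine pancreas markers were above 0 (0.00517, adjusted p = 0.557 with an estimated correlation), with 0 passing by either count. The pancreas list did not pass without POR-null quercetin array 3 (median 0.126 in place of 0.997, adjusted p = 0.579) or wild-type quercetin array 1. The acute phase list did not pass without POR-null quercetin array 1 (adjusted p = 0.103). Which lists passed differed between the diets, but no list's difference between diets held as an interaction (lowest adjusted p = 0.726 with an estimated correlation). The count fell to 199 and 142 without wild-type quercetin arrays 1 and 2 and to 127 and 173 without POR-null quercetin arrays 1 and 2. It rose to 1052 with array weights and 950 when only these groups were fitted.

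Across 12393 genes the genotype differences on the diets, which share no arrays, correlated at r = 0.593 (Spearman's rho = 0.417). Of 154 genes called on the control diet and 309 on the quercetin diet, 73 were shared as higher and 9 as lower, where independent lists would share 2.12 and 0.25, and 0 were called in opposite directions. Of the 154 genes, 152 had the same sign on the quercetin diet.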

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

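The tests of the pancreas markers and of the wild-type control arrays in this part were chosen after the results were seen. By camera with the preset correlation the quercetin response differed between genotypes for 11 lists. As the median log2 response in POR-null minus that in wild type, it was higher for exocrine pancreas markers (1.05), cholesterol synthesis (0.49), circadian clock (0.23), acute phase (0.21), heat shock (0.19), fatty acid synthesis (0.16) and oxidative phosphorylation (0.067). It was lower for stellate cell and matrix markers (-0.077), bile acid and biliary transport (-0.10), endothelial markers (-0.16) and male-biased liver genes (-0.35). None of these differences held with an estimated inter-gene correlation (lowest adjusted p = 0.726). With single arrays left out, 2 of the 11 lists kept their call throughout.

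The exocrine pancreas markers varied most between arrays. Prss2, a trypsinogen, reached 10.3 in POR-null quercetin array 3 against 7.25 in wild-type quercetin array 1. All 11 markers were highest in POR-null quercetin array 3, and 9 of the 11 exceeded the median of all values in the 12-array mean. With group means removed, the median correlation of a marker with the mean of the others was 0.99, which is consistent with pancreatic acinar tissue carried over into some pools during dissection. On the control diet the mean of the markers, relative to all arrays, ran from -0.81 to 1.08 in wild type. In POR-null on that diet it ran from -0.92 to 0.80, so the markers also varied without quercetin. A response to quercetin in POR-null liver stays open but was not needed for the shift. The mean shift turned from 0.69 to -0.16 when POR-null quercetin array 3 was left out.

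Cholesterol synthesis, heat shock and clock genes were lower with quercetin in wild type, where control arrays 2 and 3 stood apart, though none of these lists held with an estimated correlation (adjusted p = 0.659, 0.649 and 0.461); fatty acid synthesis genes and macrophage markers shared this dependence (-0.034 in place of -0.19, and -0.012 in place of 0.23). Against wild-type control array 1 alone the mean shift of the cholesterol synthesis list was 0.0042 in place of -0.45, that of heat shock genes -0.11 in place of -0.37 and that of clock genes -0.10 in place of -0.27. This restates the gap between array 1 and arrays 2 and 3, which stayed within 2 SE over arrays for each list (cholesterol synthesis -0.68, SE 0.42), so a difference between pools and a response to quercetin cannot be told apart. A different time of day at sampling could shift clock genes, but genes of the Arntl phase moved by -0.042 with an SE over arrays of 0.11, which cannot decide it either. The rules for the SE and for the gap between control arrays were set after first results were seen.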

How the results depend on the processing

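Median centring, the fits with wild-type control array 1 as the lone control and the averaged genotype contrast were added after seeing the data; a lone array is assumed to vary like the other groups. The pseudocount alternatives were not run, since the values were logarithmic. Quantile normalization, median centring and the robust prior kept every count of calls within 1.5 times, though Lcn2, Orm2, Ppp1r3c, Hsd17b6 and Sdc4 lost their quercetin-diet calls with the robust prior. For quercetin in wild type, 1 probe set passed without the 40% of lowest probe sets, 1 without the intensity trend, 1 against wild-type control array 1 alone and 2 with the replicate block. By genotype on the control diet, 30 passed when only these groups were fitted, 110 as genes (fewer tests) and 29 against control array 1 alone (fewer arrays). On the quercetin diet, 1052 passed with array weights and 950 with only these groups. Averaged over diets, 1714 probe sets and 1061 genes passed. The causes of these changes in count were not tested. On the control diet 154 genes passed by their representative probe sets, against 110 by the mean of their probe sets. With each array left out in turn, counts ranged from 0 to 151 for quercetin in wild type, 0 to 4 in POR-null, 0 to 24 averaged and 0 to 1 for the interaction. They ranged from 35 to 756 for genotype on the control diet, 127 to 389 on the quercetin diet and 991 to 2128 averaged. The correlation of the quercetin responses ranged from 0.0603 to 0.174. Of 44 control-diet genes named as passing, 4 passed in all alternatives and with each array left out, and of 12 on the quercetin diet, 6. The median of acute phase genes in the interaction ranged from 0.0545 (without POR-null quercetin array 1) to 0.305. At 0.0545 camera's direction turned while the median stayed above 0. The pancreas markers with quercetin in POR-null ranged from -0.12 (without POR-null quercetin array 3), a turned direction, to 1.33. Against control array 1 alone the direction turned for macrophage markers with quercetin (-0.0345) and cholesterol synthesis by genotype (0.33). There the median of fatty acid synthesis genes with quercetin also turned, to 0.033, while camera's direction stayed. Residual correlations of arrays with the same pool number were low (-0.17 to 0.24) but the highest for the own number in 8 of 12 pairings. Every pairing of wild type with POR-null on the same diet was among these 8 (r = 0.041 to 0.24). A shared processing batch was therefore not excluded. The block used 1 pool number across all 4 groups, so a pairing of the genotypes within each diet was not modelled. With the block, 241 and 489 probe sets passed by genotype on the control and quercetin diets and 0 in the other quercetin contrasts. Of the genes named as passing on the control diet, 4 lost their call with the block, Cyp3a11 among them.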

Other observations

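The tests of the clock phases, of POR-null control array 3 and of the urea cycle list, the permutation of list means and the averaged genotype contrast were chosen after the results were seen; the counts of other splits were planned before those splits were made. Averaged over diets, 1714 probe sets passed by limma, 1104 higher and 610 lower in POR-null. Outside the fixed lists, the genes with large increases included S100a10 (1.14 ± 0.11), an annexin partner, the TGF-beta receptor Tgfbr2 (1.12 ± 0.13), the alanine aminotransferase Gpt2 (1.13 ± 0.16), Serpinb1a (1.33 ± 0.21), Upp2, a uridine phosphorylase (1.34 ± 0.18), and the ammonium transporter Rhbg (1.09 ± 0.13). The steroid enzymes Hsd17b6 (-1.40 ± 0.25) and Hsd11b1 (-0.82 ± 0.11), the hepcidin gene Hamp2 (-0.95 ± 0.18), Osgin1 (-1.18 ± 0.26) and Dusp6, a phosphatase of ERK (-0.79 ± 0.18) were lower. These genes were chosen after their values were seen.

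In an exact permutation of genotype within diet (400 relabelings, two-sided, adjusted over 31 lists), the list mean of lipid droplet genes differed by 0.64, of CAR and PXR targets by 0.74, of fatty acid synthesis genes by 0.37, of female-biased genes by 0.38 and of urea cycle and amino acid genes by 0.15. Each had adjusted p = 0.031 and exact p = 0.005, the smallest the relabelings can give. These relabelings, those of diet and the splits counted below ignored the pool numbers, for which a shared batch was not excluded. Acute phase genes (0.46), conjugation genes (0.25) and adipocyte markers (0.25) had adjusted p = 0.0388, PPARA and fatty acid oxidation (0.12) and interferon genes (0.17) 0.0465, and male-biased genes (-0.45) did not pass at 0.0564. Some lists share members, so these results are not independent. Fabp4 is in the lipid droplet and adipocyte lists, and Sult1e1 in the conjugation and female-biased lists. Cyp2b9, Cyp2b13, Cyp3a16, Cyp3a41a and Cyp3a44 were set in both the CAR and PXR and the female-biased lists, though not every set member was measured.

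One hypothesis was that urea cycle and amino acid genes respond to quercetin in both genotypes. The list kept its shift in wild type against control array 1 alone, at 0.27 against 0.26 with all 3. Its mean was higher by 0.21 averaged over genotypes, and in an exact permutation of diet within genotype its p was 0.005, the smallest that 400 relabelings can give. Adjusted over the 31 lists it was 0.155, the smallest adjusted value a single list can reach, so chance stays open; the first rule had used the unadjusted p and would have excluded it, and was changed after the result was seen. A second hypothesis was that a different time of day lowered the clock genes in POR-null liver on the control diet. Genes of the Arntl phase (Arntl, Npas2, Clock, Cry1 and Nfil3) moved by -0.27 with an SE over arrays of 0.11, and those of the Dbp and Per phase by -0.28 with an SE of 0.15. The comparison assumed that a change of time of day would move these phases in opposite directions, which was not tested. Against wild-type control array 1 alone the Arntl phase moved by -0.076 with an SE of 0.15, so time of day stays open. Requiring that second comparison was decided after the first, which alone would have argued against it.

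POR-null control array 3 lay nearer to wild type than the other arrays of its group. On a linear scale between wild-type quercetin (0) and POR-null quercetin (1), its median position was 0.324 over 231 genes called higher on the quercetin diet and 0.512 over 78 called lower, against 0.938 and 0.886 in array 1 and 0.594 and 0.607 in array 2. Wild-type RNA in the pool may be a candidate explanation, and would place both sets at the same point. The difference was -0.19 with an SE of 0.04. Each SE in this paragraph comes from resampling genes within 1 array. It treats genes as independent and does not measure the spread between arrays. However, wild-type control array 3 differed by -0.20 with an SE of 0.09 without any such mixture, so mixing and a weaker response cannot be told apart. That comparison was added after the first result, which alone would have argued against mixing.

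Other splits of the same arrays were counted for each contrast. For POR-null against wild type, 1 of 10 splits of the 6 arrays gave as many calls on either diet, and it was the real one. There were 262 calls against at most 6 in another split on the control diet and 527 against 0 on the quercetin diet, but 10 splits are too few for a share under 0.05. For quercetin in wild type and in POR-null the real count was 0, which all 10 splits reach whatever the data, with at most 2 calls in another. For quercetin averaged over genotypes and for the interaction it was also 0, which all 100 splits within genotype reach, with at most 7 in another. These comparisons with 0 therefore decide nothing about chance. For the averaged genotype contrast, added after seeing the data, 1 of 100 splits within diet gave as many calls. It was the real one with 1714 calls, and the highest other gave 402. Chance is therefore unlikely, as far as 100 splits can show.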
